A study of Mus musculus with 6 samples.

How the data were processed

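Hearts of male mice were profiled on 6 Affymetrix expression arrays in 3 groups of 2 arrays. The groups were a transgenic line with high cardiac expression of fatty acid synthase (FASN), a transgenic line with low cardiac expression, and age-matched B6 controls. Total RNA was isolated with the RNeasy Midi kit and turned into biotin-labelled cRNA. The labels number 2 samples per group and do not say whether these came from separate hearts. All 6 samples, controls included, carry a tissue label that calls the heart transgenic, so the groups were taken from the titles and the phenotype label.

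The authors deposited 1 table with a linear signal intensity per probe set and array, and the submitters' processing notes name GCOS, the array maker's software. Its version, its summary algorithm and its scaling target are not given in the sources used here. The mean of each deposited column after trimming 2% at each end was 300.002, and these means differed by far less than the 10% that had been set as the limit for rescaling, so the deposited scaling was kept. Scanner files and detection calls were not used here. The lowest deposited values per array lay between 0.0545 and 0.158 and the 99th percentiles between 9503.8 and 10664, so signal over background could be judged only from the intensity itself.

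The table held 45101 probe sets. After 64 control probe sets had been set aside, 45037 remained, of which 34945 had 1 gene symbol in the annotation table supplied with the data, 932 had several and 9160 were not listed there. Probe sets with several symbols or none were tested but are not named. Updating the symbols through Entrez identifiers and the RefSeq genes of GRCm38.p6 altered 0 of them. Of the panel of genes fixed in advance, Cpt1b had no named tested probe set.

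Values were analysed as log2(signal + 16) in R 4.3.3 with limma 3.58.1. Fold changes are on this scale, which understates the change of dim genes. A probe set was tested if its mean over the 6 arrays was at or above the median of all non-control probe sets, which left 22519. One linear model with 3 group means was fitted to all arrays (lmFit, then eBayes with an intensity trend; 3 residual and 6.43 prior degrees of freedom). Calls used Benjamini-Hochberg adjusted p below 0.05, two-sided. The same model on simulated arrays for the high line against control recovered 22 of 49 probe sets planted at a log2 difference of 0.5, 39 of 49 at 1 and 49 of 49 at 2, with 13 unplanted calls among 22519 probe sets.

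The 37 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with one probe set per gene (the brightest), and again with the correlation estimated for each list. The second test uses only the 3 residual degrees of freedom, so it has little power over 37 lists at any correlation. The matrix list in the high line had an estimated correlation of -0.0113, below the preset value. Its unadjusted camera p still went from 1.75e-10 to 0.00491. Loss in the second test does not by itself show that a list was a product of inter-gene correlation. Correlation did matter where its estimate was high. Oxidative phosphorylation between the lines, at 0.644, went from an unadjusted camera p of 9.47e-15 to 0.189. The heat shock list in the high line, at -0.027, went from 8.28e-07 to 0.0119. For lists with a high estimated correlation the preset test may overstate the evidence. Named genes are Fasn, the 8 largest rises and 8 largest falls among called probe sets with 1 symbol, up to 4 members with the smallest p of each list described, and a fixed panel of 21 cardiac, lipid and matrix genes. Any other name is marked as chosen after its values were seen. Results were recomputed with quantile normalization, median centring, other pseudocounts, other filters, other variance models, only the 4 arrays compared, the replicate number as a block, one probe set per gene, and each array left out. Cyclic loess and a threshold of 1 on the log2 scale were added after the data had been seen. Random lists matched on brightness were drawn 10000 times. They hold unrelated genes, so a percentile among them takes no account of inter-gene correlation. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.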

Results

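Gene expression was measured in hearts of mice that carried a FASN transgene under the alpha-MHC promoter, which is active in heart muscle cells. FASN makes palmitate from acetyl-CoA and malonyl-CoA. The design asks how the heart transcriptome differs between a line with high cardiac FASN, a line with low cardiac FASN and control mice, with 2 arrays in each of the 3 groups. Signals are in arbitrary units, and the number of arrays limits the precision. Over the 22519 tested probe sets, which leave out the dim ones, arrays of one group correlated at 0.987 to 0.990 and arrays of different groups at 0.969 to 0.977 (Pearson's r across probe sets, which are not independent replicates). Nothing in the labels says that the 2 arrays of a group came from separate hearts, so the p-values measure the spread between these arrays, which may be technical.

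The transgene's own gene separated the groups. The Fasn probe set read 2268 and 2104 in the high line, 462 and 481 in the low line, and 213 and 187 in controls. The means were 2186 ± 116, 471 ± 13.3 and 200.3 ± 18.5 (SD, n = 2). Fasn was higher than in control by 3.35 ± 0.0928 on the log2 scale (SE) in the high line (limma, adjusted p = 5.58e-08) and by 1.17 in the low line (adjusted p = 3.83e-05), and the lines differed by 2.18 (adjusted p = 5.14e-06). The species of the transgene is not given in the sources used here, so this mouse probe set may read the transgene, the mouse gene or both.

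The comparison of the high line with control asks what accompanies strong cardiac FASN expression. Each FASN level is represented by a single line, so the level cannot be told apart from anything else that differs between the lines and the B6 controls. Several genes of fatty acid synthesis rose. Scd1, the desaturase that makes oleate, rose from 597 ± 15.4 to 14597 ± 929 (SD, n = 2), a 23.8-fold change. Acly, which supplies cytosolic acetyl-CoA, rose by 1.43 on the log2 scale, the elongase Elovl6 by 2.47, and Acaca, which makes malonyl-CoA, by 1.63. Elovl6 was dim in control (36.9 and 38.7), so the size of its rise is uncertain. Of 24 measured members of the list, 10 rose, 1 fell and 13 did not pass; adjusted over the list alone, 14 rose and 1 fell. The list passed with a median of 0.28 (limma camera, adjusted p = 2.57e-06), and its adjusted p = 0.149 with an estimated correlation. Markers of fat moved with it. Of 15 adipocyte genes, 9 rose and 0 fell (adjusted over the list alone, 12 rose), with a camera adjusted p = 2.67e-08 and an adjusted p = 0.139 with an estimated correlation; Scd1 and Thrsp are on both lists. The hormone Adipoq rose from 118 ± 28.7 to 3333 ± 215, Car3 by 3.67 on the log2 scale and Ucp1, the uncoupling protein of brown fat, from 8.24 ± 2.84 to 822 ± 33.4. The brown fat list passed (5 rose and 1 fell of 11; adjusted over the list alone, 6 and 1; adjusted p = 0.00245, adjusted p = 0.122 with quantile normalization, and adjusted p = 0.222 with an estimated correlation). Secretory genes of the airway rose as well. Scgb1a1 went from 4.33 ± 2.63 to 1147.5 ± 24.5 and Bpifa1 from 20.7 ± 11.2 to 1180 ± 6.5.

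**Figure D1:**
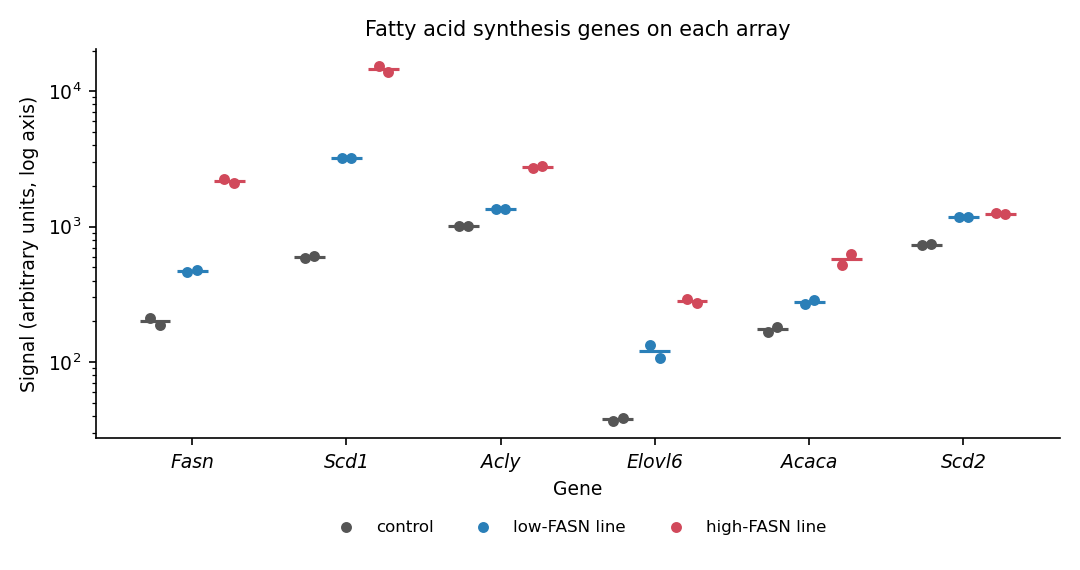
Signal (arbitrary units, log axis) of 6 fatty acid synthesis genes on each array; points are arrays, bars are means of 2 arrays, and colours mark control, low-FASN and high-FASN hearts. Fasn reads 2268 and 2104 in the high line against 213 and 187 in control.

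**Figure D2:**
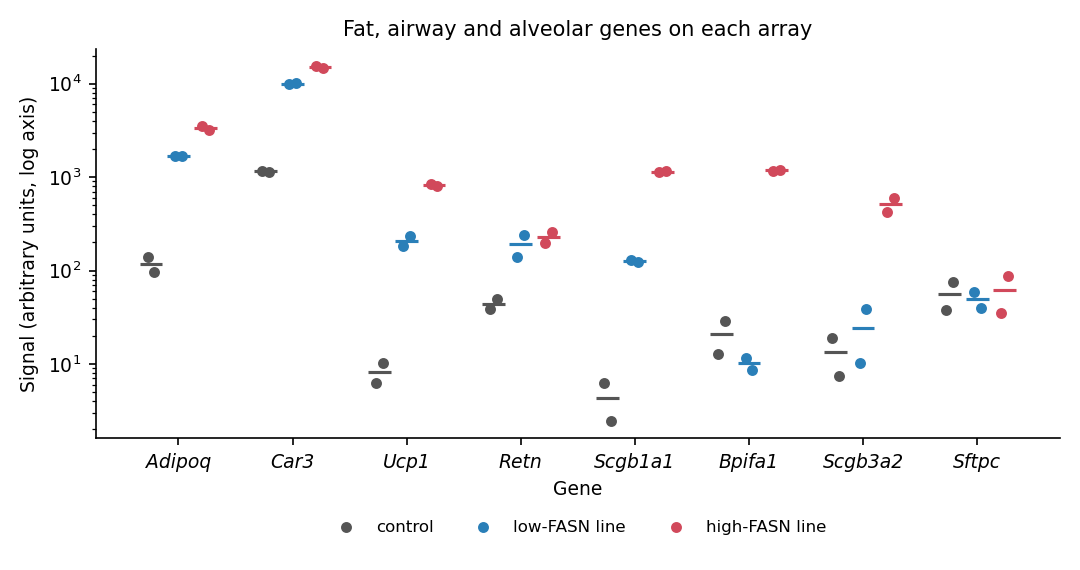
Signal (arbitrary units, log axis) of fat genes (Adipoq, Car3, Ucp1, Retn), airway genes (Scgb1a1, Bpifa1, Scgb3a2) and the alveolar gene Sftpc (chosen after its values were seen) on each array; points are arrays and bars are means of 2 arrays. Bpifa1 averages 1180 in the high line, 10.1 in the low line and 20.7 in control, while Sftpc averages 61.6, 49.5 and 56.6.

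Extracellular matrix genes rose in the high line. Of 39 measured members, 23 rose, 2 fell and 14 did not pass (adjusted over the list alone, 25 rose and 3 fell), with a median of 0.475, a camera adjusted p = 6.47e-09 and an adjusted p = 0.139 with an estimated correlation. The fibrillar collagen gene Col3a1 rose from 4060 ± 168 to 10135 ± 461, Col1a1 from 261 ± 2.92 to 499 ± 11.1, Col1a2 by 0.80 on the log2 scale, and Postn, a matrix protein of activated fibroblasts, by 0.58. Fibroblast markers (8 rose and 0 fell of 18; adjusted over the list alone, 8 and 1; adjusted p = 0.00189, and adjusted p = 0.228 with an estimated correlation) and smooth muscle markers (9 rose and 1 fell of 15, the same adjusted over the list alone; adjusted p = 0.000201, and adjusted p = 0.149 with an estimated correlation) also passed. Among the latter Acta2 rose by 1.22 and Myh11 by 1.04. Upk3b and Lrrn4, genes of the mesothelium, the outer lining of the heart and lung, were also higher in both lines. Mesothelial genes were not tested as a list of their own. Upk3b read 527 ± 5.62 in the high line, 653 ± 5.99 in the low line and 266 ± 3.17 in control, and Lrrn4 330 ± 10.8, 346 ± 29.8 and 156 ± 21.2. The lung and mesothelial list passed in the high line (6 rose and 0 fell of 13, the same adjusted over the list alone; adjusted p = 0.00113, and adjusted p = 0.198 with an estimated correlation) and not in the low line (adjusted p = 0.0622). Among the 6 that rose in the high line were the airway genes Scgb1a1, Scgb3a1 and Scgb3a2, by 5.84, 1.39 and 4.18. The pass is therefore not a result on the mesothelium alone. Natriuretic peptide genes rose slightly, Nppa by 0.33 and Nppb by 0.23, and the slow myosin gene Myh7 rose by 0.82. The brightest probe sets, Nppa among them, shifted by a median of 0.11 in the high line. The list of hypertrophy and fetal genes passed there (10 rose and 3 fell of 22, camera adjusted p = 0.0134, and adjusted p = 0.454 with an estimated correlation). In the low line it did not pass (adjusted p = 0.397, but 0.0267 with quantile normalization).

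Stress and inflammatory genes were lower in the high line. In the heat shock list 11 of 25 members fell and 1 rose (adjusted over the list alone, 14 fell and 2 rose), with Hspa1a lower by 1.58, Hspa1b by 1.35 and Hsp90aa1 by 0.99 on the log2 scale (camera adjusted p = 7.66e-06, and adjusted p = 0.147 with an estimated correlation). Among proteasome and atrophy genes 12 of 33 fell and 1 rose (adjusted over the list alone, 15 fell), including the mitophagy receptor gene Bnip3, the transcription factor gene Foxo3 and the sarcomeric ligase gene Trim54 (adjusted p = 8.06e-06, and adjusted p = 0.149 with an estimated correlation). The metallothionein gene Mt2 was 5.90-fold lower, at 1334 ± 15.2 against 7946 ± 379. The ketone body enzyme gene Bdh1 was 6.33-fold lower and the Z-disc gene Myot 5.10-fold lower. The chemokine gene Ccl9 was 4.95-fold lower, and Lcn2 fell from 259 ± 1.68 to a dim 44.3 ± 4.95; 9 of 24 inflammatory genes fell and 2 rose (adjusted over the list alone, 9 and 3), with adjusted p = 0.000915 and adjusted p = 0.149 with an estimated correlation. Macrophage markers fell as well (6 of 24 fell and 0 rose; adjusted over the list alone, 7 and 0; adjusted p = 0.00245, and adjusted p = 0.149 with an estimated correlation), and the largest fall of a named gene was that of Ms4a6d, a membrane protein gene of myeloid cells, at 6.58-fold lower. The neutrophil gene S100a8 fell from 188 ± 8.89 to 70.0 ± 13.8 and S100a9 from 99.6 ± 10.7 to a dim 31.4 ± 3.77. Their list, blood markers, did not pass (3 of 9 fell and 1 rose, the same adjusted over the list alone, camera adjusted p = 0.273).

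In all, 3234 of 22519 probe sets differed between the high line and control, 1843 higher and 1391 lower (57% higher, and 47.8% with median centring), and 362 of them by at least 1 on the log2 scale. Of the 37 lists 24 passed, 15 up and 9 down, and 0 passed with an estimated correlation (10 at an unadjusted p below 0.05). The latter test rests on 3 residual degrees of freedom and has little power over 37 lists. The probe set count fell to 1411 without control array 2 and to 1612 without control array 1, and an untrended variance model gave 1233.

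The comparison of the low line with control asks the same of weak FASN expression, with the same limit. The lipogenic genes moved less. Scd1 rose to 3210 ± 8.34 (5.26-fold), Scd2 by 0.66 and Acaca by 0.62 on the log2 scale, while Oxsm, a mitochondrial fatty acid synthesis gene, fell by 0.79. Of 24 list members 8 rose and 3 fell (the same counts adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0622). Adipoq rose to 1680 ± 2.06, Car3 to 10039 ± 122 and Ucp1 to 208 ± 32.7, although the brown fat list did not pass (2 rose and 2 fell of 11; adjusted over the list alone, 4 and 3; adjusted p = 0.957). The adipocyte list passed with 7 rises and 2 falls among 15 (adjusted over the list alone, 8 and 2; adjusted p = 0.0117, and adjusted p = 0.264 with an estimated correlation). Scgb1a1 rose to 126 ± 4.98, while Bpifa1 stood at 10.1 ± 2.17.

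Matrix genes rose in the low line. Of 39 members 24 rose and 2 fell (adjusted over the list alone, 25 and 2), with a median of 0.55, a camera adjusted p = 1.03e-08 and an adjusted p = 0.184 with an estimated correlation. Col3a1 rose to 13372 ± 281, Col1a1 to 755 ± 24.2, Postn to 2921 ± 134, and the elastin gene Eln by 2.19 on the log2 scale. Fibroblast markers rose too (11 rose and 0 fell of 18; adjusted over the list alone, 12 and 0; adjusted p = 0.00117, and adjusted p = 0.329 with an estimated correlation). Lymphocyte genes rose, led by the immunoglobulin genes Ighm (1720 ± 12.7 against 45.0 ± 49.6) and Jchain (432 ± 12.8 against 46.7 ± 4.32); of 19 list members on the arrays 7 were bright enough to be tested and 6 rose, the same adjusted over the list alone, with adjusted p = 0.000862 and adjusted p = 0.248 with an estimated correlation. Of 4 tested Ighm probe sets, a dimmer one fell by 0.82 in the low line. The lymphocyte list passed upward in the high line as well (3 of 7 rose and 0 fell, camera adjusted p = 0.0109, and adjusted p = 0.182 with an estimated correlation). Cell division genes rose too, Mki67 by 1.71 and Top2a by 1.12, with 9 rises and 1 fall among 20 (adjusted over the list alone, 10 and 1; adjusted p = 0.00854, and adjusted p = 0.248 with an estimated correlation).

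**Figure D3:**
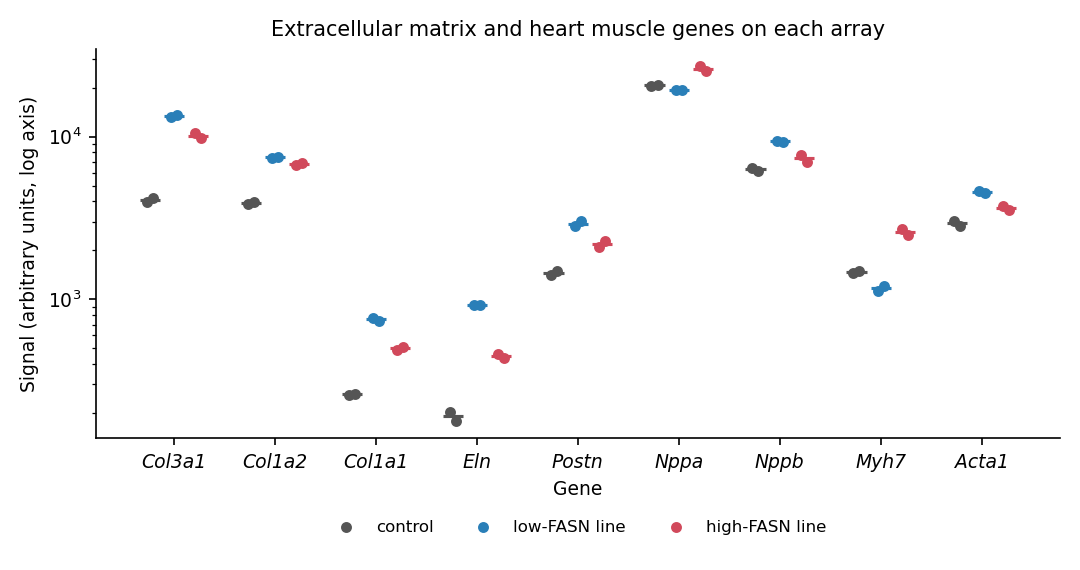
Signal (arbitrary units, log axis) of extracellular matrix genes (Col3a1, Col1a2, Col1a1, Eln, Postn) and heart muscle genes (Nppa, Nppb, Myh7, Acta1) on each array; points are arrays and bars are means of 2 arrays. Col3a1 averages 13372 in the low line, 10135 in the high line and 4060 in control.

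Genes of defence against oxidation fell in the low line (16 of 30 fell and 3 rose; adjusted over the list alone, 16 and 4), with Mt2 5.19-fold lower, Mt1 lower by 1.17 and Cat by 0.47 on the log2 scale (camera adjusted p = 7.71e-05, and adjusted p = 0.189 with an estimated correlation). This list passed downward in the high line too (8 fell and 2 rose, adjusted p = 0.000915, and adjusted p = 0.149 with an estimated correlation). The difference between the lines did not pass (adjusted p = 0.221). In the heat shock list 13 of 25 fell and 1 rose (adjusted over the list alone, 14 and 1; adjusted p = 2.7e-06, and adjusted p = 0.184 with an estimated correlation), and among proteasome and atrophy genes 18 of 33 fell and 3 rose, with Trim54 lower by 1.71 (adjusted over the list alone, 20 and 3; adjusted p = 7.71e-05, and adjusted p = 0.248 with an estimated correlation). Bdh1 was 6.87-fold lower, Myot 5.27-fold lower, and the chemokine gene Cxcl14 fell from 344 ± 6.45 to a dim 47.1 ± 23.7. Inflammatory genes passed downward as a list, as in the high line (8 of 24 fell and 1 rose, camera adjusted p = 0.00919, and adjusted p = 0.248 with an estimated correlation). Ppara, the nuclear receptor that drives fatty acid oxidation genes, fell from 1467 ± 16.2 to 580 ± 21.1. Nppb rose by 0.58 and the skeletal actin gene Acta1 by 0.63, Myh7 fell by 0.32, and Nppa stood at -0.10 (adjusted p = 0.167), a sign that turned to 0.020 with quantile normalization.

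In all, 5475 probe sets differed between the low line and control, 3045 higher and 2430 lower, and 596 of them by at least 1 on the log2 scale. Of the 37 lists 16 passed, 5 up and 11 down, and 0 passed with an estimated correlation (7 at an unadjusted p below 0.05). The probe set count was 2884 without low-line array 1, 2905 without low-line array 2, 3398 without control array 1 and 3223 without control array 2, and an untrended variance model gave 3576.

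**Figure D4:**
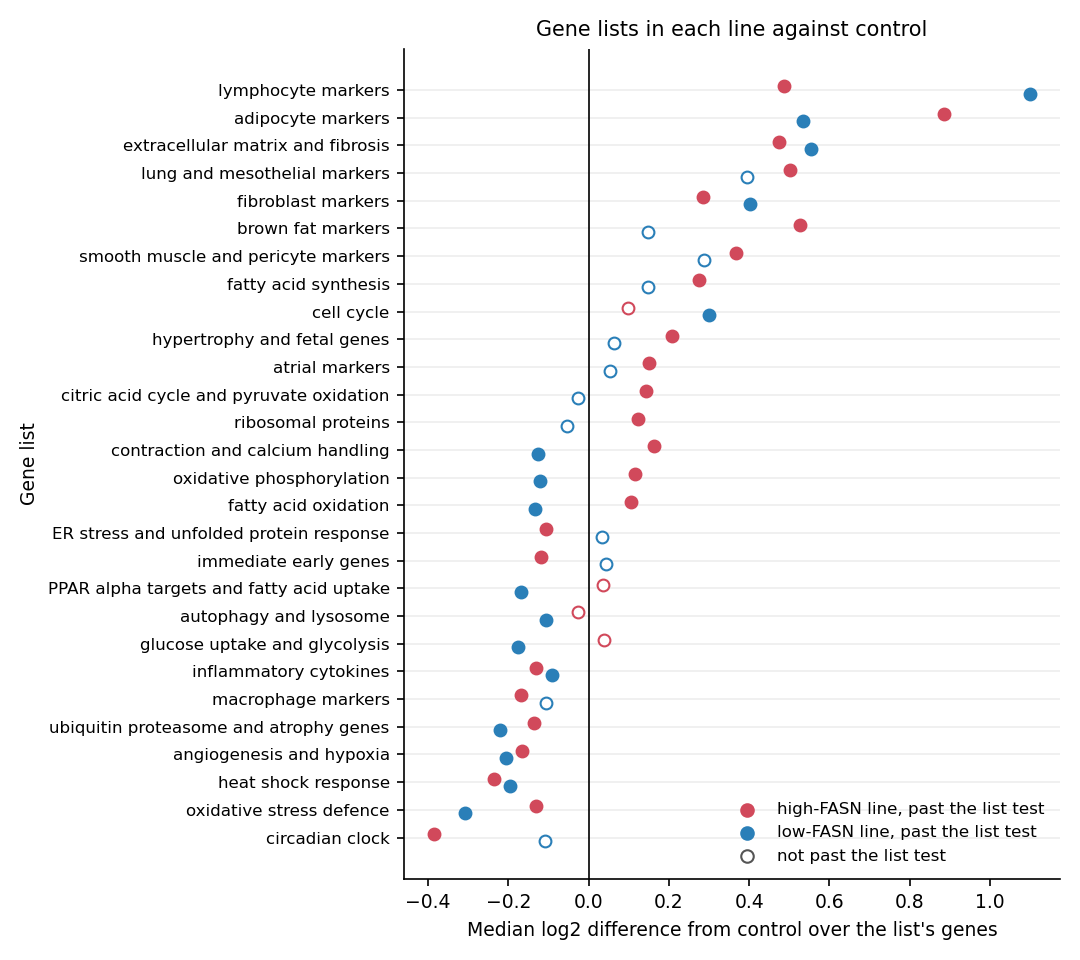
Median log2 difference from control over the genes of each list that passed in at least 1 line, for the high line (red) and the low line (blue); filled points passed limma's camera at a preset correlation, open points did not. The matrix list sits at 0.475 and 0.55; oxidative phosphorylation sits at 0.12 and -0.12, which became -0.012 in the high line with quantile normalization and 0.020 in the low line with cyclic loess, and contraction sits at 0.16 and -0.13, which became 0.0044 with quantile normalization and 0.016 with cyclic loess in the low line.

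The lines were also compared with each other. Beside Fasn, Scd1 was 4.52-fold higher in the high line, Acly higher by 1.01 and Acaca by 1.01 on the log2 scale; 10 of 24 fatty acid synthesis genes were higher and 0 lower (the same counts adjusted over the list alone), with a camera adjusted p = 5.85e-06 and an adjusted p = 0.237 with an estimated correlation. Adipoq was 1.97-fold and Ucp1 3.75-fold higher in the high line, and the airway gene Scgb1a1 was 8.20-fold higher; Bpifa1 read 1180 ± 6.5 in the high line and a dim 10.1 ± 2.17 in the low line (SD, n = 2). Matrix genes were lower in the high than in the low line (11 lower and 5 higher of 39; adjusted over the list alone, 13 and 6; adjusted p = 0.00539, and adjusted p = 0.237 with an estimated correlation), with Eln lower by 1.01 and Col3a1 by 0.40. Ighm was 5.15-fold and the immediate early gene Fos 4.90-fold lower in the high line. Myh7 was 2.20-fold higher in the high line. Ppara was 1.75-fold higher there on its brightest probe set. Its other probe sets differed by 0.38 and 0.255 on the log2 scale, the latter not called (limma adjusted p = 0.0592). Against control Ppara was lower in the high line too, with log2 differences of -0.51, -0.66 and -0.56 in the same order.

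Mitochondrial and contractile genes were higher in the high than in the low line at the deposited scaling. Of 47 oxidative phosphorylation genes 34 were higher and 1 lower (adjusted over the list alone, 40 and 1), with a median of 0.24 that became 0.0036 with quantile normalization (camera adjusted p = 3.5e-13, adjusted p = 0.663 with quantile normalization, adjusted p = 9.52e-06 and a median of 0.10 with cyclic loess, and adjusted p = 0.328 with an estimated correlation). Of 33 contraction genes 21 were higher and 2 lower (adjusted over the list alone, 22 and 2), with a median of 0.29 that became 0.071 with quantile normalization and 0.17 with cyclic loess (adjusted p = 5.57e-08, then 0.0492 and 2.55e-05, and adjusted p = 0.328 with an estimated correlation). Fatty acid oxidation genes followed (12 higher and 1 lower of 22; adjusted over the list alone, 13 and 2; adjusted p = 0.000153, adjusted p = 0.327 with quantile normalization, adjusted p = 0.0053 with cyclic loess and adjusted p = 0.293 with an estimated correlation). The hybridization controls, which are added to each sample, were higher in the high line by a median of 0.27 on the log2 scale.

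In all, 4179 probe sets differed between the lines, 2181 higher and 1998 lower in the high line (52.2% higher, and 46.4% with median centring), and 314 of them by at least 1 on the log2 scale. Of the 37 lists 18 passed, 13 up and 5 down, and 0 passed with an estimated correlation (7 at an unadjusted p below 0.05). The probe set count was 1577 without low-line array 1 and 1554 without low-line array 2, and 1449 with an untrended variance model; 11 lists passed with quantile normalization.

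Both lines were compared with the same 2 control arrays, so their differences from control are linked by design. Of the tested probe sets, 1038 were higher in both lines, 746 lower in both and 100 changed in opposite directions, against 249.2, 150.1 and 387 for independent lists of these sizes, which do not share controls. The correlation of the fold changes across probe sets was 0.60, against 0.50 in 100 simulations of unchanged groups that shared their controls, and the covariance was 0.0945 against 0.0160. With each line set against a control array of its own, a check added later, 439 and 461 probe sets were higher in both lines in the 2 possible assignments (65.3 and 73.1 for independent lists), 345 and 342 lower in both (38.2 and 41.3) and 20 and 23 opposite (100 and 110), with correlations of 0.44 and 0.43. What the 2 control arrays have in common is not removed by this.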

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

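The tests of fat composition, of alveolar lung, of the agreement within pairs, of brightness and of the hybridization controls were chosen only after the results had been seen; the test of further airway genes was written before their values were looked at.

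Several results differed in direction between the lines. Against control and at the deposited scaling (oxidative phosphorylation became -0.012 in the high line with quantile normalization), the lists of fatty acid oxidation, oxidative phosphorylation and contraction were higher in the high line and lower in the low line, and the lines differed by medians of 0.23, 0.24 and 0.29 on the log2 scale. Most members did not pass singly against control. In the order given, 1 of 22, 10 of 47 and 13 of 33 rose in the high line, and 9, 8 and 10 fell in the low line. None of these list calls held with an estimated correlation (in the order given, adjusted p = 0.448, 0.548 and 0.486 in the high line and 0.386, 0.601 and 0.626 in the low line). That test has little power at any correlation. The estimated correlations were 0.126, 0.644 and 0.448, well above the preset 0.01, so the preset test may overstate the evidence for these lists. With quantile normalization only the contraction call of the high line was kept (adjusted p = 0.0498). The others were lost: fatty acid oxidation (0.552 in the high line, also 0.251 with median centring, and 0.321 in the low line), oxidative phosphorylation (0.552 and 0.996) and contraction in the low line (0.749, with a median of 0.0044). Cyclic loess, added after seeing the data, kept the calls of the high line (camera adjusted p = 0.00371, 1.41e-08 and 2.37e-06 in the order given). It lost those of the low line (0.429, 0.437 and 0.891). Myh7 rose in the high line and fell in the low line, a difference of 1.14 between them. For 100 probe sets the 2 lines changed in opposite directions from the same controls, which all but ensures a called difference between the lines.

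The first pattern is the close agreement of the 2 arrays of each group. If the arrays came from separate hearts, genes that vary between animals (immediate early, clock, blood, lymphocyte, airway and fat genes) would differ more within pairs than other genes of the same brightness. Over 101 such genes the ratio was 1.2 in control, 1.15 in the low line and 0.951 in the high line (percentiles 93.6, 83.9 and 31.5 of brightness-matched random sets). The highest ratio, 1.2, stayed below the limit set for arrays that carry independent hearts. That limit was set after the data were seen and without arrays known to come from separate hearts, so the ratios cannot decide the question. Pooled RNA from several hearts would give such ratios, and so would closely matched animals. As the labels do not say that the hearts were separate, a difference between the groups may hold for these RNA samples without holding for the lines.

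The second pattern is the rise of fat and airway genes in the transgenic hearts. Fat of one composition that differed only in amount would give each fat gene the same ratio of the high to the low line's excess over control. The ratios ran from 1.26 for Retn (0.781 to 2.24 over pairs of arrays) to 4.07 for Ucp1 (3.54 to 4.73), 3.23 times apart. These ranges do not overlap, which argues against fat of one composition, although the variable Retn makes the size of the gap imprecise. A mixture of brown and white fat in unlike proportions, or induction in the heart, stays open. With white and brown fat of fixed expression, no gene could exceed the ratio of Ucp1 (up to 4.73 over pairs of arrays), and Fasn at 7.33 and Scd1 at 5.36 did (lowest pairs 6.79 and 5.09), as did Acly at 5.02, whereas Elovl6 at 2.96, Acaca at 3.9 and Me1 at 1.38 did not, so for these last 3 genes such fat stays open. Alveolar lung is argued against by Sftpc, which differed by 0.058 with an upper 95% limit of 0.921. Airway epithelium was tested on 14 airway genes not looked at before (of 34, the others too dim to be tested or not on the arrays). In the high line their median lay at percentile 99.9 of brightness-matched random sets of unrelated genes, and 5 rose and 0 fell. The epithelial genes Epcam (-0.123) and Spint2 (-0.0791) were not called there. Of the 5 that rose, Lypd2 (2.07 and 1.69) and Fxyd3 (1.27 and 1.14) rose in the high and in the low line. In the low line the percentile was 81.9, and 2 rose and 1 fell. Without the filter on dim probe sets, added later, 32 genes gave 99.9 and 56.4. Airway epithelium thus fits the set's median in the high line, though not every member, and for the low line it was not settled. The bound set by Ucp1 covers a mixture of white and brown fat alone. Airway epithelium was not part of it, and its gene Scgb1a1 averaged 1147 in the high line against 125.9 in the low line. Scd1 and Acly above the bound therefore do not exclude tissue that came with the hearts. For Fasn the probe set may read the transgene. An effect of the transgene on the fat and airway genes was not tested apart from these sources.

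The third pattern is the opposite direction of mitochondrial and contractile genes in the 2 lines. The 560 probe sets with a mean above 13 on the log2 scale shifted by 0.11 in the high line and -0.10 in the low line, and lists drawn at the same brightness placed the oxidative phosphorylation median at percentile 42.4 and 14.6, so a shift of the brightest probe sets may account for it. A stricter draw, added after that result and leaving out the mitochondrial and contractile lists, gave 83.5 and 3.17, the latter close to the edge of the central range, and put the difference between the lines at 99.7 (93 in the first draw; fatty acid oxidation 99.7 and 99.1; contraction 100 in both), so brightness may not account for all of it. The hybridization controls were higher in the high than in the low line by 0.271, 18 of 18 probe sets, so a step after the hearts were taken is also open. The contraction list lay above the matched lists in the high line (percentile 99.8, or 99.9 in the stricter draw) but not in the low line (10.6, or 6.56). Matched lists had a median of 0.0899 against its 0.163, which became 0.068 with quantile normalization and 0.157 with cyclic loess. The random lists hold unrelated genes, while contraction and oxidative phosphorylation had estimated correlations of 0.448 and 0.644. Genes that move together give extreme medians more often, so the high percentiles overstate the evidence. Whether a part beyond brightness remains is therefore not settled, and an effect of the transgene on such a part stays open.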

How the results depend on the processing

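Fasn kept its direction and its call in all 3 comparisons under every alternative that was run. With an array left out its log2 difference ranged from 3.26 to 3.44 (high line against control), 1.09 to 1.26 (low line against control) and 2.12 to 2.23 (high against low line). Of 436 calls of named genes other than Fasn, 284 held under every alternative in which their probe set was tested. The other 152 were lost under at least 1, of which 2 reversed. Stricter filters left some of these probe sets untested, and the run with one probe set per gene was not applied to them.

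The counts of changed probe sets depended most on a threshold for the size of the difference, then on the variance model and on single arrays. In the order high line against control, low line against control and high against low line, untrended eBayes gave 1233, 3576 and 1449, a difference of at least 1 on the log2 scale (added after seeing the data) gave 362, 596 and 314, and one probe set per gene gave 3449 and 2609 for the last 2, where fewer probe sets were tested. With an array left out the counts ran from 1411 to 3497, from 2884 to 6486 and from 1554 to 4184; a group's lone array was then assumed to vary like the other groups. List counts ran from 21 to 24, 15 to 18 and 17 to 19 with an array left out. They were 0 in each comparison with an estimated inter-gene correlation, a test with only 3 residual degrees of freedom. Quantile normalization gave 11 lists for the high against the low line.

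With quantile normalization the list medians of oxidative phosphorylation became -0.012 (high line against control) and 0.0036 with the test turned downward (high against low line), that of the citric acid cycle became -0.031 (high against low line), and Rps29 (-0.0088, high line against control) and Cox8b (-0.031, high against low line) changed sign. With cyclic loess, added after seeing the data, the low line's medians of oxidative phosphorylation and contraction became 0.020 and 0.016, while those of the high line were 0.109 and 0.157. Both methods remove shifts that depend on brightness; beyond that the cause was not tested.

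Replicate numbers did not pair the arrays (correlations of deviations 0.0396, 0.0273 and 0.000398). The replicate block gave 3392, 5647 and 4325 probe sets and 24, 16 and 18 lists. Without detection calls, the limit that background sets on dim genes is not known.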

Other observations

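The glucocorticoid test below, its repeat without genes of tested lists, and the comparisons of probe sets were chosen only after the results had been seen.

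The immediate early genes Egr1 and Fos, which respond within minutes to hours, were highest in the low line. Egr1 rose by 2.40 and Fos by 2.21 on the log2 scale in the low line, and Fos averaged 1144 ± 86 there against 234 ± 9.29 in control (SD, n = 2). As a list, the immediate early genes did not pass in the low line (9 rose and 8 fell of 25, camera adjusted p = 0.996) and passed downward in the high line (6 fell and 3 rose, adjusted p = 0.0147, and adjusted p = 0.182 with an estimated correlation). Between the lines 11 were lower and 2 higher in the high line (adjusted p = 0.00896, and adjusted p = 0.237 with an estimated correlation). In the high line Per2 fell by 1.43 and 10 of 21 clock genes fell and 2 rose (adjusted p = 0.000348, and adjusted p = 0.157 with an estimated correlation). In the low line 8 clock genes fell and 5 rose, among them Dbp by 0.70 and Per3 by 1.12, with a median of -0.11, and the list did not pass (adjusted p = 0.459), nor did the difference between the lines (adjusted p = 0.0559).

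Some ion channel genes differed between the lines. Of 27 list members 10 were higher and 1 lower in the high than in the low line (adjusted p = 0.00127, and adjusted p = 0.237 with an estimated correlation), while against control the list passed in neither line (adjusted p = 0.169 and 0.123). In the low line the sodium channel subunit gene Scn4b fell by 1.68, and the potassium channel subunit gene Kcne1, against the direction of the list, rose by 2.56. Genes of protein folding in the endoplasmic reticulum were lower in the high than in the low line (12 lower and 1 higher of 35, adjusted p = 0.00061, and adjusted p = 0.264 with an estimated correlation), with Manf lower by 0.94 and Pdia3 by 0.65. Angptl4, an inhibitor of lipoprotein lipase, rose 3.99-fold in the high line and 3.17-fold in the low line.

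Probe sets of one gene did not always move together. For Myh6 the bright probe set (30523 in control) rose by 0.25 in the high line while the dimmer one (2243.8 in control) fell by 0.22 there and rose by 0.62 in the low line. For Atp2a2 the dim probe sets (514.9 and 456.8 in control) rose by 0.90 and 1.01 in the low line, where the brightest stood at -0.11 (0.018 with quantile normalization). The control probe set for the 3' end of 18S ribosomal RNA read 9387 ± 161 in the low line, 20459 ± 1580 in the high line and 18787 ± 503 in control, and the repeat control AFFX-MURINE_b1_at read 1602 ± 4.24, 1683 ± 13.5 and 3313 ± 42.4. The ratio of 3' to 5' signal, a measure of RNA integrity and labelling, also separated the groups. For Gapdh it was 0.813 and 0.798 in the low line, 0.905 and 0.881 in the high line and 0.954 and 0.953 in control, and for actin 2.31 and 2.32, 2.52 and 2.40, and 2.62 and 2.71. What these ratios contribute to the differences between the groups was not tested.

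Several genes that fell in both lines (Mt2, Zbtb16, Fkbp5, Lcn2) are induced by glucocorticoids, hence the hypothesis that glucocorticoid exposure differed between transgenic and control mice. The hypothesis and the gene list were chosen after these falls had been seen. Of the other list genes whose values had been seen, Serpina3n, Fam107a and Ccl9 also fell in both lines. Per1 fell in the low line only (-0.0705 in the high line, limma adjusted p = 0.781). Pdk4 was called in neither line (adjusted p = 0.0542 in the high and 0.053 in the low line). Of 24 further genes, 9 of which (Mt1, Lyve1 and others) belong to gene lists that had already been tested, 9 fell and 5 rose in the high line and 16 fell and 2 rose in the low line. Their medians of -0.18 and -0.50 lay at percentile 0.05 and at percentile 0 of 10000 brightness-matched random sets. Such sets hold unrelated genes, so these percentiles overstate the evidence if the genes move together. Without those 9 genes, a check added later, 4 of 15 fell and 2 rose in the high line and 10 fell and 1 rose in the low line, with medians of -0.16 and -0.54 at percentiles 0.63 and 0. Lower glucocorticoid exposure of the transgenic mice may thus account for part of the shared falls; handling, time of day and housing are not given in the sources used here, and the control arrays used for both link the 2 lines.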
